A study of Mus musculus with 12 samples.

How the data were processed

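Bulk RNA-seq libraries were made from established B16F10 tumours of the mouse, B16F10 being a melanoma cell line that grows as a transplanted tumour. Per the labels' protocols, total RNA was extracted with a column kit, libraries were made with a standard mRNA kit, and both ends of the fragments were sequenced on an Illumina HiSeq instrument. The labels place 12 libraries in 4 groups of 3: vehicle, birinapant (named SMAC in the titles), immune checkpoint blockade (ICB, antibodies against PD-1 and CTLA-4) and birinapant with ICB, called the combination here. They do not say that the libraries of a group came from separate mice, so the p-values measure the spread between these samples, part of which may be technical.

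The authors deposited a table of whole-number read counts for 18131 gene symbols in the 12 libraries. Per the submitters' processing notes, STAR, RSEM, DESeq2 and the genome build mm10 were used, without roles, order or versions, and the gene annotation is not given in the sources used here. The notes do not say whether the counts are rounded RSEM estimates, nor how 18131 genes were chosen. Only 1 of these genes had a count of 0 in every library. The authors also deposited a table of log2 values for 15711 of these genes. Each value equals log2 of the count plus 0.5, taken as CPM (scaled counts) with 1 constant per library in place of the total, and that constant was 0.982 to 1.04 times the total count. This table served only as an alternative input. No other column of values per sample was left unused.

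Total counts per library ranged from 16390948 to 29333838, with a median of 20405623.5, and the 10 most abundant genes took 6.75% to 7.51% of the counts. Counts within a group differed by more than sampling noise in each pair of libraries, with a chi-square per degree of freedom of 6.10 to 59.8, so no library was counted as a copy of another. Intervals and floors given for low counts cover counting error only. The floor is 3 counts over the libraries of a group. For genes with 1 to 3 counts in a group, the ratio of pooled CPM is given with its exact Clopper-Pearson interval at 95% confidence.

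Counts were analysed as deposited in R 4.3.3. Genes were kept by filterByExpr of edgeR 4.0.16 on the groups, which left 14715 genes; those left out held at most 0.0873% of a library's counts. TMM scaling and the quasi-likelihood test with robust estimation were used in 1 fit of all 12 libraries with a mean per group, which leaves 8 residual degrees of freedom. 8 contrasts were tested, two-sided: each treatment and the combination against vehicle, the combination against each treatment alone, the interaction, and the effect of each treatment averaged over the presence of the other. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Standard errors of log2 fold changes were computed from the F statistic. The median standard error over all genes was 0.185 for birinapant against vehicle. No covariate was used.

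31 gene lists, with 610 genes in all, were fixed before the data were examined, for antigen presentation, checkpoints, interferon, NF-kB, cell death, stress, proliferation and the cell types a tumour sample could hold. Of these genes 564 were in the count table and 520 were tested. 29 lists had at least 5 tested members; the lists for NK cells and for B and plasma cells had 4 each and were not tested. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 29 lists. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Per list, the members called over all genes tested and those called when p-values were adjusted over the list alone were counted. No list was chosen on these samples. List levels per library are means of log2 CPM with a prior count of 2.

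The genes named were chosen by a rule fixed before the data were examined. It takes a panel of 27 genes for MHC class I presentation, PD-L1, NF-kB, T cells, chemokines and melanocytes. It adds the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, or the 5 smallest p where fewer than 5 passed. It also takes up to 4 members per described list with the smallest p. Predicted gene models are counted and not named. Ifng, a member of the panel, did not pass the count filter, which left 26 panel genes tested. Of 375 named genes, 374 matched a single gene of the GENCODE mouse annotation for GRCm38, the assembly that mm10 denotes, from which coordinates were taken. Members of the H2, Gbp, Oas, Ly6, Bcl2a1, Serpina3, haemoglobin and keratin families share sequence with close copies, and how the authors' counting divided such reads is not given in the sources used here. Their single values are therefore uncertain, and so are those of genes that overlap others, since the labels do not say that the libraries keep the strand.

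The fit was tested on simulated counts for 14504 genes with known changes. For birinapant against vehicle it recovered 58.6% of 99 genes changed 2-fold and 85.7% of 98 changed 4-fold, with 6 unchanged genes among 148 calls. For birinapant averaged it recovered 66.7% and 93.9%, with 9 unchanged genes among 167 calls. In simulated data with no change under ICB it called 0 genes for ICB against vehicle. The simulated genes varied independently of one another, without shared differences in cell content between libraries, so these rates may not hold for the real libraries. The alternatives tried were DESeq2 1.42.0, RLE scaling, no count filter, a mean count of at least 50, voom with quality weights and the deposited log2 table. Others were fits of only the 2 groups compared, a replicate block and leaving out each library in turn. The number in the titles, as 8 or lower against higher, was also tried as a covariate. Added after seeing the data were the keratinocyte list level as a covariate and leaving out combination replicates 2 and 3.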

Results

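Transcripts were measured in established B16F10 melanoma tumours under 4 treatments, with 3 libraries each: vehicle, birinapant, ICB and the combination. Birinapant is a SMAC mimetic, a small molecule that binds inhibitor of apoptosis proteins such as cIAP1 and cIAP2, and ICB joined antibodies against the T cell checkpoints PD-1 and CTLA-4. The series title sets out to separate the expression of MHC class I, which shows antigens to CD8 T cells, from that of PD-L1, the ligand of PD-1. Each library held between 16390948 and 29333838 counts, and 14715 genes were tested. The first principal component took 39.9% of the variance and the second 17.0%. Combination replicate 3 stood apart on the second, at 66.8 against -39.8 to 20.6 in the other 11 libraries.

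Markers of other cells differed between the libraries. The keratinocyte list, genes of the epidermis, had a mean log2 CPM of 3.65, 5.88 and 6.90 in the combination libraries and between -2.05 and 0.77 in the other 9. Combination replicate 3 also had the highest levels of the neutrophil list, 3.19, and the fibroblast list, 5.23. Its MHC class I list stood at 5.42, against 7.44 and 7.56 in the other 2 combination libraries. Birinapant replicate 2 had the highest red cell list level, 8.41, against at most 5.70 elsewhere. The melanocyte and melanoma list lay between 8.57 and 9.04 in all 12 libraries.

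**Figure D1:**
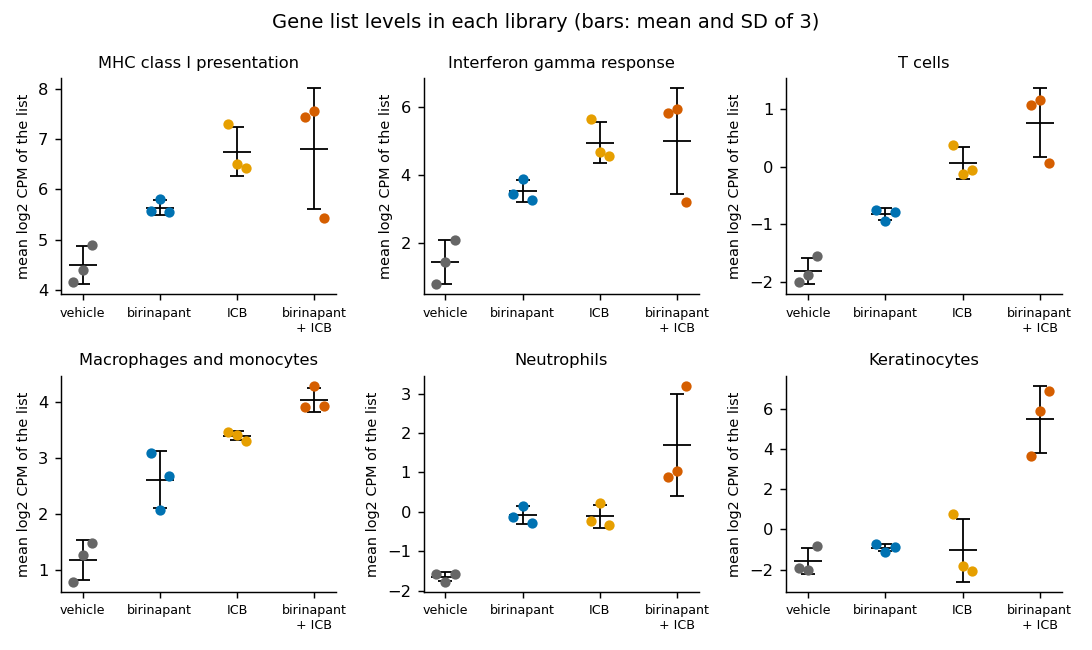
Mean log2 CPM of 6 gene lists (vertical axes) in each library, by treatment group, with bars for the mean and SD of 3 libraries. The keratinocyte list reached 3.65 to 6.90 in the combination libraries and at most 0.77 elsewhere, and MHC class I stood at 5.42 in combination replicate 3.

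Birinapant was first set against vehicle, the comparison that shows what the SMAC mimetic did alone. 8 genes passed the test, all higher, with n = 3 per group. Ccl8, a chemokine that attracts monocytes and T cells, rose 7.80-fold (log2 2.96 ± 0.41, SE; adjusted p = 0.0246), from 1.17 ± 0.397 to 9.31 ± 5.69 CPM (SD, n = 3). C3, the central protein of complement, rose 5.25-fold (adjusted p = 0.0380), and the myeloid membrane gene Ms4a6d rose 4.02-fold (adjusted p = 0.0246). Ly6a, which encodes the interferon-inducible surface protein Sca-1, rose 4.39-fold, Scml4 3.88-fold, S100a4 3.35-fold and Tgfbi, a matrix protein induced by TGF-beta, 3.32-fold. The eighth was a predicted gene model. In GRCm38, Ccl8 lies on chromosome 11 at 82115185 to 82116799 and C3 on chromosome 17 at 57203970 to 57228136.

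None of the 26 panel genes passed for birinapant alone. Among the MHC class I genes, the heavy chains H2-D1 and H2-K1 stood 2.06-fold (adjusted p = 0.405) and 1.55-fold (adjusted p = 0.656) above vehicle, and the light chain B2m 2.05-fold (adjusted p = 0.369). Cd274, which encodes PD-L1, stood at 1.54-fold (log2 0.62 ± 0.46, adjusted p = 0.582). The drug's targets cIAP1 and cIAP2, encoded by Birc2 and Birc3, were at 1.12-fold and 1.17-fold, and Nfkb2 and Relb of the noncanonical NF-kB pathway at 0.899-fold and 0.857-fold. The noncanonical NF-kB list had a median log2 fold change of 0.09 over 15 genes (camera adjusted p = 0.777).

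17 of the 29 lists passed camera for birinapant, 15 higher and 2 lower; 0 passed with an estimated correlation (lowest adjusted p = 0.25) and 0 by fry (lowest adjusted p = 0.0967). The macrophage and monocyte list had a median log2 fold change of 1.46 (adjusted p = 8.22e-12, and adjusted p = 0.25 with an estimated correlation). Of its 21 members 0 passed over all genes and 14 when adjusted over the list alone, with C1qa at 3.31-fold (adjusted p = 0.0724) and Chil3 at 10.5-fold (adjusted p = 0.0940). In the complement list 1 of 14 members rose over all genes and 9 adjusted over the list alone (median 1.09, adjusted p = 1.40e-07, and 0.25 with an estimated correlation). The interferon gamma response list had a median of 2.23 over 29 genes with 0 members past the threshold and 1 adjusted over the list alone (adjusted p = 1.40e-07, and 0.397 with an estimated correlation). MHC class I presentation had a median of 0.95 with 0 of 23 past either threshold (adjusted p = 3.92e-06, and 0.397 with an estimated correlation). The unfolded protein and ATF4 list was lower (median -0.28, adjusted p = 2.65e-05, and 0.397 with an estimated correlation), with 0 of 20 members past the threshold and 1 lower adjusted over the list alone, the cystine transporter gene Slc7a11 at 0.340-fold (adjusted p over all genes 0.188). The red cell list (median 3.05, adjusted p = 0.000325, and 0.397 with an estimated correlation) held 0 of 6 genes past the threshold and 5 adjusted over the list alone. Birinapant replicate 2 had the highest level of it, 8.41 against 5.18 and 4.60 in the other 2 birinapant libraries and 3.67 to 4.53 in vehicle. The neutrophil list (median 1.62, adjusted p = 0.00053, and 0.397 with an estimated correlation) had 0 of 11 members past the threshold and 3 adjusted over the list alone. The fibroblast list (median 0.59, adjusted p = 0.00391, and 0.601 with an estimated correlation) had 0 of 20 past either threshold and was lost without birinapant replicate 3 (0.123).

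The 8 calls rested on the libraries and the tool. There were 0 without vehicle replicate 1 or 2, 3 without vehicle replicate 3, 1 without birinapant replicate 1 and 24 without birinapant replicate 2, and each of the 7 named genes lost its call without at least 1 library. DESeq2 called 222 genes, 173 higher and 49 lower, among them the 8, and voom with quality weights called 2.

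The comparison of ICB with vehicle shows the response to the antibodies alone. 330 genes passed, 318 higher and 12 lower. Cd8a, a chain of the CD8 coreceptor, rose 28.3-fold (log2 4.82 ± 0.75, SE, n = 3 per group; adjusted p = 0.00447). Gzmb, the cytotoxic protease granzyme B, had 2 counts in the vehicle libraries and 252 with ICB, a ratio of 122 (counting interval 33.5 to 1017; adjusted p = 0.00691). The interferon-inducible genes Oas3, Ifi205, Apol6 and Sp110 rose 19.5-fold, 28.3-fold, 65.6-fold and 20.2-fold. Gbp8, an interferon-inducible GTPase, had 0 counts in vehicle and was at least 94.3-fold higher. Acod1, the itaconate-producing enzyme of activated macrophages, rose 27.8-fold (adjusted p = 0.00234), the noncoding RNA AW112010 21.5-fold and Cd74, the MHC class II invariant chain, 19.1-fold (adjusted p = 0.0375).

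Of the panel, H2-D1 rose 5.09-fold (log2 2.35 ± 0.50, adjusted p = 0.0457) and B2m 4.53-fold (log2 2.18 ± 0.43, adjusted p = 0.0287), while H2-K1 at 3.94-fold did not pass (adjusted p = 0.175). H2-D1 lost its call without any vehicle library or ICB replicate 1 or 2 (adjusted p = 0.0764 to 0.231), and B2m without vehicle replicate 1 or 2 or ICB replicate 1 or 2 (0.0663 to 0.145). Cd274 stood at 3.85-fold (log2 1.94 ± 0.47) with an adjusted p of 0.0661. The CXCR3 ligand Cxcl10 rose 2.94-fold (adjusted p = 0.00481), and Cxcl9 at 18.6-fold did not pass (adjusted p = 0.0860). Cd3e, part of the T cell receptor complex, had 2 counts in vehicle and 50 with ICB (ratio 24.3, counting interval 6.38 to 206; adjusted p = 0.00878). Without vehicle replicate 1 Cd3e and Gzmb did not pass (0.0581 and 0.0512). The genes that fell changed less. By the naming rule the largest falls were in the teneurin gene Tenm4 (3.58-fold lower, adjusted p = 0.0177) and the homeobox gene Hoxb9 (3.04-fold lower, adjusted p = 0.0386), followed by Fbxl7, Ppp1r16b and Gria4 at 1.86-fold, 1.79-fold and 1.73-fold lower.

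Under ICB 18 lists passed camera, 16 higher and 2 lower. 5 of them also passed with an estimated correlation: macrophages and monocytes (adjusted p = 0.0286), checkpoints (0.0286), complement (0.0365), T cells (0.0365) and NF-kB and TNF targets (0.0365). In the macrophage and monocyte list 15 of 21 members rose over all genes and 20 adjusted over the list alone, among them C1qa 5.50-fold, Cd68 2.56-fold and Csf1r 4.31-fold. In the T cell list 4 of 20 rose and 13 adjusted over the list alone, and in the checkpoint list 8 of 16 rose and 10 adjusted over the list alone, such as Vsir 4.16-fold and Havcr2 3.38-fold. Of the complement list 7 of 14 rose, with Cfb at 5.59-fold, and 12 adjusted over the list alone. In the type I interferon list (median 2.70) 11 of 30 rose and 28 adjusted over the list alone, with an adjusted p of 0.148 with an estimated correlation. In the interferon gamma list (median 3.80) 7 of 29 rose and 27 adjusted over the list alone, with an adjusted p of 0.104 with an estimated correlation. MHC class I presentation (median 2.18) had 4 of 23 members higher, H2-Q6, H2-Q7, B2m and H2-D1, and 20 adjusted over the list alone, with an adjusted p of 0.102 with an estimated correlation. Cytotoxic lymphocyte genes (median 3.80) had 7 of 16 higher and 14 higher adjusted over the list alone, with an adjusted p of 0.102 with an estimated correlation. The unfolded protein and ATF4 list was lower (median -0.27, adjusted p = 2.68e-06, and 0.165 with an estimated correlation) with 0 of 20 members past either threshold. The melanocyte and melanoma list was higher (median 0.27, adjusted p = 0.0123, and 0.406 with an estimated correlation) with 0 of 20 past the threshold; it did not pass without vehicle replicate 1 or 3 or ICB replicate 1 or 3 (0.0795 to 0.180).

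The 330 calls became 64, 98 and 166 without vehicle replicates 1, 2 and 3 and 101 without ICB replicate 1. DESeq2 called 677 genes, 584 higher and 93 lower, including 329 of the 330.

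**Figure D2:**
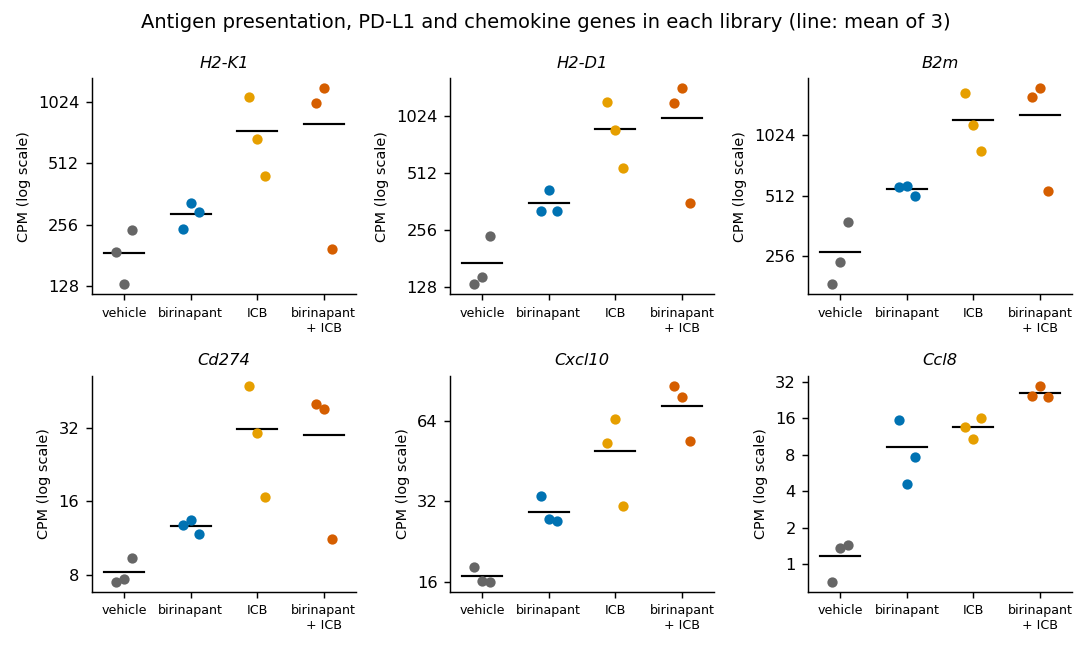
CPM on a log scale (vertical axes) of 6 genes in each library, by treatment group, with a line at the mean of 3. Cd274 averaged 8.19 CPM in vehicle, 12.7 with birinapant, 31.6 with ICB and 29.8 in the combination, where replicate 3 lay at 11.2.

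The combination against vehicle gave the largest number of calls of the 8 contrasts, 1638 genes, of which 1163 were higher and 475 lower. By the naming rule, keratins were among the largest rises. Krt14, a keratin of basal keratinocytes, was at 89.8, 404 and 1445 CPM in the combination libraries and averaged 0.0567 CPM in vehicle (adjusted p = 0.00399). Krt10 and Dmkn had 0 counts in vehicle and were at least 2322-fold and 1340-fold higher, Fcgbp and the epidermal transcription factor gene Trp63 at least 204-fold and 180-fold. Krt6a, Krt6b, Krt17, Sprr1a and Lor, the last a protein of the cornified envelope, rose as well (adjusted p = 0.00339 to 0.00881). In the keratinocyte list 15 of 17 genes rose and 17 adjusted over the list alone (median 9.58, or 7.95 with the 2 genes absent from vehicle at their bound; adjusted p = 7.61e-10, and 0.185 with an estimated correlation). The skeletal muscle list (median 1.75, 4 of 20 higher, 15 adjusted over the list alone) and the fibroblast list (median 2.0, 7 of 20 higher, 15 adjusted over the list alone) stood above vehicle too, with adjusted p = 0.304 and 0.287 with an estimated correlation. Under the keratinocyte covariate, hard to part from the group, skeletal muscle and fibroblasts turned to lower and did not pass camera (adjusted p = 0.0668 and 0.869).

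Immune genes rose beside them. Ccl8 rose 21.8-fold (log2 4.44 ± 0.42, SE, n = 3 per group), C3 11.5-fold, Cd8a 45.4-fold (adjusted p = 0.000619) and the complement receptor gene Itgam 7.50-fold (adjusted p = 2.82e-05). All 21 macrophage and monocyte genes rose, for example C1qa 8.54-fold and Csf1r 6.97-fold (21 adjusted over the list alone, median 2.93, adjusted p = 1.97e-19, and 0.0511 with an estimated correlation). In the T cell list 15 of 20 rose and 19 adjusted over the list alone (median 3.64, adjusted p = 0.0511 with an estimated correlation). In the neutrophil list 10 of 11 rose and 10 adjusted over the list alone, such as Csf3r 9.15-fold (median 3.85, adjusted p = 0.185 with an estimated correlation). Combination replicate 3 had the highest level of this list and of the keratinocyte list, 3.19 and 6.90. Under the keratinocyte covariate, hard to part from the group, the neutrophil list did not pass camera (adjusted p = 0.445). Whether its RNA came from neutrophils or from skin was not tested. In the interferon gamma list 26 of 29 rose and 28 adjusted over the list alone (median 4.21, adjusted p = 0.185 with an estimated correlation). In total 21 lists passed camera, 0 with an estimated correlation and 17 by fry.

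Of the panel 17 of 26 genes rose in the combination. H2-D1 rose 5.81-fold (adjusted p = 0.0115, and 0.0589 without vehicle replicate 1), B2m 4.79-fold (adjusted p = 0.00818), Tap1, a peptide transporter into the endoplasmic reticulum, 11-fold (adjusted p = 0.0289) and the immunoproteasome subunits Psmb8 and Psmb9 42.6-fold and 34.3-fold. H2-K1 stood at 4.29-fold with an adjusted p of 0.0566. 12 of the 17 lost their call under at least 1 alternative, among them Tap1 without vehicle replicate 1 or 2 or combination replicate 1 or 2 (0.0647 to 0.122), and Psmb8 and Psmb9 without any 1 vehicle library (0.0523 to 0.0742 and 0.0610 to 0.0908). In the MHC class I list 19 of 23 rose and 22 adjusted over the list alone (median 2.43, adjusted p = 0.185 with an estimated correlation). Cd274 rose 3.63-fold (log2 1.86 ± 0.47, adjusted p = 0.0287); its adjusted p was 0.121, 0.0831 and 0.0796 without vehicle replicates 1, 2 and 3 and 0.0806 and 0.0779 without combination replicates 1 and 2. Birc3 rose 1.87-fold (adjusted p = 0.0122, and 0.0784 without vehicle replicate 1), while Birc2 was not called (log2 0.06 ± 0.17, adjusted p = 0.865). In GRCm38 Cd274 lies on chromosome 19 at 29367455 to 29388095, B2m on chromosome 2 at 122147686 to 122153083, H2-D1 and H2-K1 on chromosome 17 at 35262730 to 35267499 and 33996017 to 34000347.

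Among the 475 genes that fell in the combination, Fgf21, a hormone gene induced by metabolic stress, fell most by the naming rule (15.6-fold lower, adjusted p = 0.00536), followed by Hoxb9 (6.15-fold), Lgi4 (5.14-fold), P2rx3 (5.09-fold), Tenm4 (4.55-fold) and the proline synthesis gene Pycr1 (4.19-fold). In the hypoxia and glycolysis list 7 of 25 fell and 0 rose, and 14 fell and 2 rose adjusted over the list alone, with Ero1l 2.10-fold, Ankrd37 2.24-fold, Mxi1 1.60-fold and the glycolytic switch kinase gene Pdk1 1.59-fold lower (median -0.38, adjusted p = 2.26e-06, and 0.185 with an estimated correlation). The ATF4 targets Slc7a11 and Asns fell 3.36-fold and 1.87-fold, the 2 of 20 in the unfolded protein and ATF4 list that did, with 7 lower and 1 higher adjusted over the list alone (adjusted p = 0.0289, and 0.511 with an estimated correlation, and 0.0540 without vehicle replicate 1). The melanocyte regulators Mitf and Sox10 fell 1.60-fold (adjusted p = 0.0182) and 1.46-fold (adjusted p = 0.0422), while the melanocyte and melanoma list as a whole did not pass (median 0.22, adjusted p = 0.429). Mitf had an adjusted p of 0.0609 without vehicle replicate 3 and 0.0564 without combination replicate 3.

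With the keratinocyte list level as a covariate 0 genes passed for the combination against vehicle by edgeR, 822 at an unadjusted p under 0.05, and leaving out combination replicates 2 and 3 left 710 genes, 618 higher and 92 lower, 619 of them among the 1638. Without vehicle replicates 1 and 3 there were 722 and 991 genes; no other single library moved the count by over 1.5 times.

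**Figure D3:**
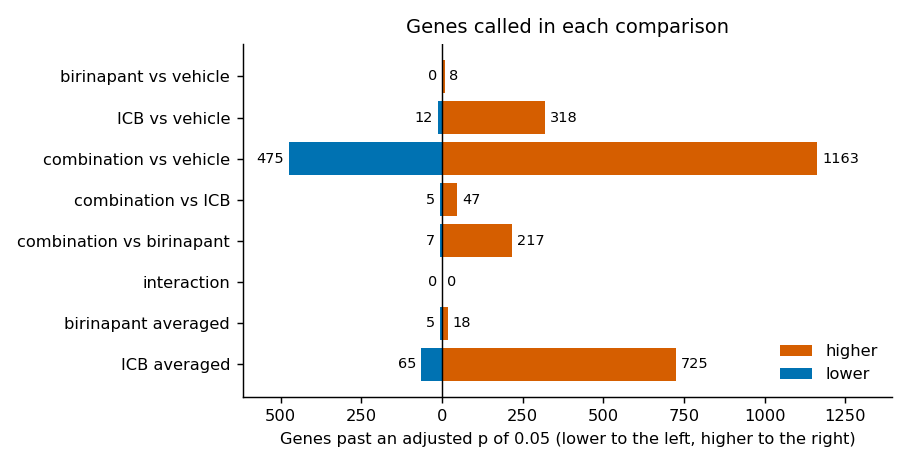
Number of genes past an adjusted p of 0.05 in each of the 8 contrasts (horizontal axis; lower to the left, higher to the right). The combination against vehicle had 1163 higher and 475 lower genes, and the interaction had 0.

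The ICB and combination responses share the vehicle libraries. 311 genes passed higher and 9 lower in both, against 25.1 and 0.387 for independent lists; simulated unchanged groups shared at most 1. Across genes the fold changes correlated at r = 0.770 (simulated 0.499), with a covariance of 0.638 against a simulated 0.0745. For birinapant and ICB, 7 genes passed higher in both, against 0.173 for independent lists and at most 1 simulated, with a covariance of 0.350 against 0.0742. For birinapant and the combination 7 did, against 0.632 and 0 simulated, with a covariance of 0.499 against 0.0751. Genes are not independent replicates. The 3 vehicle libraries cannot be split into 2 parts of 2, so part of each excess may come from the shared vehicle libraries. Some contrasts share no library. For ICB against vehicle and the combination against birinapant, 93 genes passed higher in both, against 4.69 for independent lists (r = 0.506 across genes). For birinapant against vehicle and the combination against ICB 0 did, against 0.0256 (r = 0.352).

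The combination was then set against ICB, groups that differ in birinapant and in the level of skin genes. 52 genes passed, 47 higher and 5 lower, and keratins were again among the largest rises. Krt6a, Krt6b and Krt14 rose (adjusted p = 0.0457, 0.0457 and 0.0493), with Aqp3, Ly6d, S100a14, Lypd3 and Serpinb5 among the others. The keratinocyte list had a median log2 fold change of 6.43, with 7 of 17 higher and 17 adjusted over the list alone (adjusted p = 1.65e-15, and 0.421 with an estimated correlation). The 5 that fell were Gstm1 (1.69-fold lower, adjusted p = 0.0304), the salt-inducible kinase gene Sik1 (2.35-fold), Tcp11l2 (2.18-fold), the endothelial gene Esm1 (1.94-fold) and Mitf (1.79-fold, adjusted p = 0.0496).

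0 of the 26 panel genes passed for the combination against ICB. H2-K1, H2-D1 and B2m stood at 1.09-fold, 1.14-fold and 1.06-fold, and Cd274 at 0.943-fold (log2 -0.08 ± 0.44, SE, n = 3 per group; adjusted p = 0.958). Combination replicate 3 lowered these values. Its mean log2 CPM of the 3 MHC class I genes was 8.39, against 10.3 and 10.5 in the other 2 and 9.20 to 10.3 with ICB. Its Cd274 was 3.50, against 5.33 and 5.26 in the other 2 and 4.07 to 5.57 with ICB. Of the 26 panel genes 13 changed sign under at least 1 alternative, none of them called. The MHC class I list had a median of 0.31 (adjusted p = 0.462). The macrophage and monocyte list passed camera (median 0.69, adjusted p = 8.94e-07, and 0.421 with an estimated correlation) with 0 of 21 members past the threshold and 1 adjusted over the list alone. Skeletal muscle (median 1.88, adjusted p = 2.75e-09, 0 of 20 past the threshold, 15 adjusted over the list alone), fibroblasts (1.39, 5.28e-08, 0 of 20 past either), neutrophils (1.93, 0.000351, 0 of 11, 4 adjusted over the list alone) and adipocytes (0.41, 0.00447, 0 of 9 past either) were higher too, each at 0.421 with an estimated correlation. With the keratinocyte covariate, hard to part from the group, skeletal muscle, fibroblasts and adipocytes turned to lower and did not pass camera (0.131, 0.475 and 0.601). The T cell list (median 0.85, adjusted p = 0.00133, and 0.421 with an estimated correlation) had 0 of 20 past the threshold and 1 adjusted over the list alone. In the hypoxia and glycolysis list (median -0.29, adjusted p = 6.46e-07, and 0.421 with an estimated correlation) 0 of 25 passed and 3 were lower adjusted over the list alone, Vegfa standing at 0.559-fold. The type I interferon list was lower (median -0.12, adjusted p = 0.00535, and 0.782 with an estimated correlation) with 0 of 30 past either threshold; without combination replicate 3 it was higher (adjusted p = 1.13e-06) and without ICB replicate 1 it did not pass (0.347). 14 lists passed camera and 0 passed with an estimated correlation or by fry.

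The 52 calls became 0 without any 1 of the ICB libraries, 7 and 25 without combination replicates 2 and 3, and 292 without combination replicate 1. DESeq2 called 298 genes (222 higher, 76 lower), and 0 passed with the keratinocyte covariate, without combination replicates 2 and 3, with voom and quality weights or in a fit of only these 2 groups (196, 736, 1760 and 1677 at an unadjusted p under 0.05).

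The combination was also set against birinapant, groups that differ in the antibodies and in the level of skin genes. 224 genes passed, 217 higher and 7 lower. Beside the keratins, Cd8a rose 8.02-fold (log2 3.0 ± 0.59, SE, n = 3 per group; adjusted p = 0.0235) and Cxcl10 2.48-fold (log2 1.31 ± 0.23, adjusted p = 0.0200), the 2 panel genes that passed; each lost its call without any 1 birinapant library and without combination replicate 2 (adjusted p = 0.0765 to 0.125 for Cd8a and 0.0610 to 0.120 for Cxcl10). H2-D1, B2m and Cd274 stood at 2.82-fold, 2.34-fold and 2.36-fold with adjusted p of 0.220, 0.238 and 0.281. Itgam rose 3.35-fold (adjusted p = 0.00682) and Csf1r 2.94-fold. In the macrophage and monocyte list 7 of 21 rose and 18 adjusted over the list alone (adjusted p = 0.0421 with an estimated correlation), and in the checkpoint list 3 of 16 rose, Entpd1, Vsir and Pdcd1, and 7 adjusted over the list alone (adjusted p = 0.0421 with an estimated correlation). In the cytotoxic lymphocyte list 4 of 16 rose and 11 adjusted over the list alone (adjusted p = 0.164 with an estimated correlation). In the keratinocyte list 13 of 17 rose and 17 adjusted over the list alone (adjusted p = 0.123 with an estimated correlation). Neutrophils (median 2.47, 1 of 11 higher, 8 adjusted over the list alone), fibroblasts (1.31, 0 of 20 past either threshold), skeletal muscle (1.24, 0 of 20 past either) and adipocytes (1.03, 0 of 9, 4 adjusted over the list alone) passed camera as higher, with adjusted p of 0.162, 0.298, 0.254 and 0.0746 with an estimated correlation. Fibroblasts did not pass camera without combination replicate 3 (adjusted p = 0.220). Without combination replicates 2 and 3 the direction of fibroblasts and skeletal muscle turned to lower. Among the falls were Atp7b (2.36-fold lower), Lrrc4b (2.27-fold), Esm1 (1.98-fold), Dnm1 (1.89-fold) and Capn6 (1.62-fold). 23 lists passed camera, 2 with an estimated correlation and 8 by fry.

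These 224 calls became 41, 1 and 3 without birinapant replicates 1, 2 and 3, 414 and 500 without combination replicates 1 and 3, and 67 without combination replicate 2. DESeq2 called 550, 111 passed without combination replicates 2 and 3, and 0 passed with the keratinocyte covariate or in a fit of only these 2 groups (298 and 1291 at an unadjusted p under 0.05).

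The interaction tests whether the effect of both treatments differs from the sum of the separate effects on the log2 scale. edgeR called 0 genes, with 699 at an unadjusted p under 0.05 and a lowest adjusted p of 0.921; DESeq2 called 16, 15 higher and 1 lower, and voom with quality weights and limma on the deposited log2 values called 0 each. The 5 genes with the smallest p were Wnt10a (log2 4.94 ± 1.02, SE), Tm6sf2 (-3.89 ± 0.81), Acpp (1.03 ± 0.22), Map3k3 (0.73 ± 0.16) and Rab25 (5.01 ± 1.11), each with an adjusted p of 0.921. Cd274 had an interaction of -0.71 ± 0.64 and B2m of -0.95 ± 0.58 (adjusted p = 0.921 for each). Without combination replicate 1 there were 9 genes. 19 lists passed camera, 7 higher and 12 lower, and 0 with an estimated correlation (adjusted p = 0.429 or more) or by fry (0.523 or more).

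Averaged over the presence of ICB, birinapant changed 23 genes, 18 higher and 5 lower. Genes of myeloid cells and complement were among those that rose: Ccl8 (3.87-fold, log2 1.95 ± 0.27, SE, 6 libraries against 6; adjusted p = 0.0173), C3 (3.13-fold), the chemokine receptor gene Ccr1 (2.75-fold), Ms4a6d (2.59-fold), Tgfbi (2.49-fold), S100a4 (2.29-fold), the Fc receptor gene Fcgr3 (2.0-fold) and Itgam (1.97-fold). Ly6e and the collagen-processing gene Pcolce rose 1.94-fold and 1.45-fold. Arid5a and Tcp11l2 were 1.77-fold lower each, Esm1 1.65-fold, Irf2bp2 1.60-fold and Samd14 1.58-fold lower. None of the 26 panel genes passed by edgeR, with Cd274 at 1.21-fold (adjusted p = 0.661) and B2m at 1.47-fold (adjusted p = 0.303). The lowest adjusted p of the panel was that of Cd3e, 0.0516. DESeq2 called 5 panel genes. In the macrophage and monocyte list 1 of 21 rose, C1qa 2.27-fold, and 19 adjusted over the list alone (median 1.15, adjusted p = 5.83e-12, and 0.257 with an estimated correlation). In the hypoxia and glycolysis list (median -0.22, adjusted p = 4.08e-06, and 0.402 with an estimated correlation) 0 of 25 passed and 5 were lower adjusted over the list alone. The keratinocyte list, high in the combination libraries, moved with it (median 4.17, 0 of 17 past the threshold, 12 adjusted over the list alone, adjusted p = 1.57e-06, and 0.402 with an estimated correlation). Fibroblasts, skeletal muscle and neutrophils also passed camera as higher (adjusted p = 1.57e-06, 6.98e-06 and 1.89e-05). 17 lists passed camera, 0 with an estimated correlation and 6 by fry.

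DESeq2 called 965 genes for birinapant averaged (630 higher, 335 lower), including the 23, and the keratinocyte covariate left 0 by edgeR (671 at an unadjusted p under 0.05). Leaving out single libraries gave 7, 1 and 9 without vehicle replicates 1 to 3, 12, 62 and 293 without birinapant replicates 1 to 3, 10 and 2 without ICB replicates 1 and 2, and 270 and 250 without combination replicates 1 and 3.

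Averaged over the presence of birinapant, ICB changed 790 genes, 725 higher and 65 lower. Cyp4f18, a leukotriene-metabolising cytochrome of myeloid cells, rose 9.42-fold (log2 3.24 ± 0.29, SE, 6 libraries against 6; adjusted p = 5.42e-05), Acod1 12.4-fold, Il2rb, a chain of the interleukin 2 receptor, 8.77-fold and Fgl2 8.24-fold. Serpina3g and Serpina3f rose 10.2-fold and 9.98-fold, Ifi205 8.10-fold and Prph 8.44-fold. The desmosomal Pkp3 also passed, with 15 counts in vehicle, 31 with birinapant, 40 with ICB and 1036 in the combination, the libraries high in keratinocyte genes. 17 of the 26 panel genes rose, among them Cd8a 15.1-fold (adjusted p = 0.000382), H2-K1 3.30-fold (adjusted p = 0.0495), H2-D1 3.79-fold (adjusted p = 0.0107), B2m 3.26-fold (adjusted p = 0.00767) and Cd274 3.01-fold (log2 1.59 ± 0.32, adjusted p = 0.0174). H2-K1 lost its call without any 1 library other than combination replicate 3 (adjusted p = 0.0527 to 0.131), and Cd274 without vehicle replicate 1 or 2 or birinapant replicate 1 or 3 (adjusted p = 0.0545 to 0.0620). In all 10 of the 17 lost their call under at least 1 alternative, among them Tap1 and Nlrc5 without any 1 of 9 libraries (0.0515 to 0.0971). By the naming rule the largest falls were in Cfap46 (2.26-fold lower, adjusted p = 0.00919), Arhgap33 (2.08-fold), and Kcnj8 and Abcc9 (2.0-fold and 1.85-fold), both genes of a potassium channel found in pericytes.

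6 lists passed with an estimated correlation for ICB averaged: macrophages and monocytes (18 of 21 members higher, 21 adjusted over the list alone; adjusted p = 0.0190), checkpoints (10 of 16, 12 higher and 1 lower adjusted over the list alone; 0.0190), T cells (12 of 20, 18; 0.0214), NF-kB and TNF targets (8 of 25, 12; 0.0214), complement (11 of 14, 14; 0.0289) and lymphoid tissue chemokines (2 of 5, 3; 0.0418). In the MHC class I list 19 of 23 rose and 20 adjusted over the list alone (median 1.83, adjusted p = 0.0834 with an estimated correlation). In the interferon gamma list 26 of 29 rose and 28 adjusted over the list alone (median 2.99, adjusted p = 0.0864 with an estimated correlation). The keratinocyte list, high in the combination libraries, moved with it (median 4.87, 6 of 17 higher, 14 adjusted over the list alone, adjusted p = 1.14e-06, and 0.299 with an estimated correlation). 23 lists passed camera and 17 fry. Without vehicle replicate 1 there were 493 genes and without birinapant replicate 3 there were 511; DESeq2 called 1205 (1008 higher, 197 lower), and the keratinocyte covariate left 2.

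The question in the series title was put to the transcripts of whole tumour samples. These hold other cells beside tumour cells, so the values speak neither for tumour cells alone nor for protein. The mean log2 CPM of H2-K1, H2-D1 and B2m was 7.63 ± 0.43 in vehicle, 8.58 ± 0.15 with birinapant, 9.77 ± 0.57 with ICB and 9.72 ± 1.16 in the combination (SD, n = 3). Cd274 stood at 3.04 ± 0.17, 3.67 ± 0.10, 4.86 ± 0.75 and 4.70 ± 1.0. The difference of the 2 was 4.58 ± 0.27, 4.91 ± 0.11, 4.91 ± 0.19 and 5.02 ± 0.18. With birinapant averaged over ICB this difference stood 0.22 higher (exact permutation p = 0.0900, two-sided), and with ICB averaged over birinapant also 0.22 (exact p = 0.10); adjusted over the 21 tests of this family both stood at 0.210. For birinapant against vehicle it stood 0.32 higher (exact p = 0.200, where 0.10 is the smallest p that 3 against 3 allow) and for the combination against ICB 0.11 (exact p = 0.50). The MHC class I mean stood 1.65 higher with ICB and Cd274 1.42 higher in the averaged comparison (exact p = 0.0200 for each, 0.210 adjusted). The smallest p of an averaged comparison is 0.005, and with most of the 21 tests limited to 0.10 or more few could pass after adjustment, so these p-values do not show that the values did not differ.

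**Figure D4:**
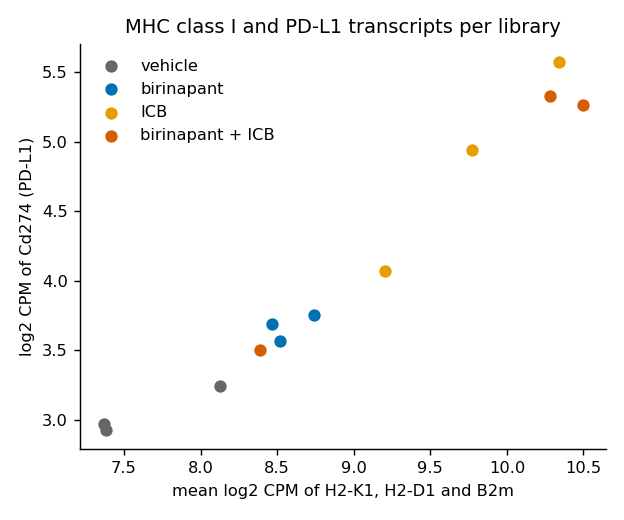
Log2 CPM of Cd274 (vertical axis) against the mean log2 CPM of H2-K1, H2-D1 and B2m (horizontal axis), 1 point per library, coloured by treatment group. The group means run from 7.63 and 3.04 in vehicle to 9.77 and 4.86 with ICB.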

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

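Of the tests below, those of the skin genes as a feature of the combination group, of leukocytes and of interferon for MHC class I, both tests of combination replicate 3, the keratinocyte covariate and the fit without combination replicates 2 and 3 were chosen after the result was seen.

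The effect of the combination differed from the sum of the separate effects in 19 gene lists by camera with a preset correlation, while 0 genes passed by edgeR (699 at an unadjusted p under 0.05; DESeq2 called 16, voom and limma 0) and 0 lists passed with an estimated correlation. Below the sum were interferon gamma response (median log2 interaction -1.63), MHC class II (-1.44), type I interferon response (-1.20), cytotoxic lymphocytes (-1.14), macrophages and monocytes (-0.76), T cells (-0.75), MHC class I (-0.69), checkpoints (-0.65), complement (-0.56), mitochondrial genes (-0.50), inflammatory chemokines (-0.44) and hypoxia and glycolysis (-0.15). Above it were keratinocytes (5.37), skeletal muscle (1.11), fibroblasts (0.62), adipocytes (0.53), endothelium (0.49), unfolded protein and ATF4 (0.35) and proliferation (0.12). Some negative values were made lower by combination replicate 3. Its mean log2 CPM for interferon gamma was 3.20, against 5.83 and 5.95 in combination replicates 1 and 2. For type I interferon it was 2.32 against 4.84 and 4.84, and for MHC class II 3.04 against 5.81 and 6.01. For cytotoxic lymphocytes it was -0.17 against 1.67 and 1.58, and for MHC class I 5.42 against 7.44 and 7.56. Its mitochondrial and inflammatory chemokine lists were instead the highest of the 3. Between 14 and 22 lists passed when 1 library was left out. T cells did not pass without vehicle replicate 1 or 2, birinapant 1, ICB 1 or combination 3 (adjusted p = 0.0719 to 0.288). Hypoxia and glycolysis did not without vehicle replicate 2 or 3, birinapant 2, ICB 2 or combination 3 (0.0904 to 0.872), nor endothelium without vehicle replicate 2, ICB 1 or combination 3 (0.0525 to 0.525). Fibroblasts did not without vehicle replicate 2 or 3, birinapant 1 or 2, ICB 1 or combination 3 (0.0772 to 0.777), turning lower without the last. Proliferation was lost without vehicle replicate 2, ICB 2 or combination 3 (0.0772 to 0.510), checkpoints without vehicle replicate 1, birinapant 1 or ICB 1 (0.0745 to 0.146), adipocytes without birinapant replicate 2 or 3 or ICB 1 (0.0560 to 0.0587) and inflammatory chemokines without combination replicate 1 (0.0553). Without combination replicates 2 and 3 fibroblasts passed as lower (0.00210), and skeletal muscle (0.794), adipocytes (0.297), endothelium and hypoxia and glycolysis (0.775 each, both turned), T cells (0.189) and proliferation (0.297) did not pass. The keratinocyte covariate ended the calls of MHC class I (0.294), MHC class II (0.204), cytotoxic lymphocytes (0.227), T cells (0.536), keratinocytes (0.803), endothelium (0.526) and adipocytes (0.769). Under it fibroblasts and skeletal muscle passed as lower (0.0112 and 0.0261) and hypoxia and glycolysis as higher (0.0112). This covariate is the level of the keratinocyte list itself, so the loss of the keratinocyte call was fixed in advance. It is high in each combination library and low in the others, so for the other lists its effect and the group's are hard to part. Since the real gene count is 0, each split must give at least as many (20 of 20 did, the highest other 2), so these splits say nothing about chance.

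For birinapant against vehicle, the splits of 3 against 3 are too few for a share under 0.05; the real count was 8 genes and the highest other 0. The same limit holds for ICB against vehicle (330, highest other 0), the combination against vehicle (1638, 0), against ICB (52, 0) and against birinapant (224, 0), each with 1 of 10 splits as large. For the averaged effects the share was under 0.05, with 60 splits drawn from 200 possible. Only 1 of 60 splits, the real one, gave as many genes for birinapant (23, highest other 0) and 1 of 60 for ICB (790, highest other 344). The other splits put libraries of unlike treatment into the same group, which can widen the spread and lower their counts. These shares, not adjusted over the contrasts, therefore do not exclude chance.

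Skin genes were high in all 3 combination libraries. The lowest of them lay 2.88 above the highest other library in the keratinocyte list, so this was no feature of 1 library, and treatment and dissection cannot be told apart in this design. A second list of 26 skin and hair follicle genes, written before it was examined, had 9 genes in the count table and 7 tested. The median log2 fold change of this list over vehicle was 1.17. Past the threshold 3 were higher, with log2 fold changes of 4.14 ± 0.60 for Cdh1, 3.49 ± 0.63 for Grhl1 and 2.86 ± 0.77 for Grhl3 (SE, n = 3). The others did not pass: Cdsn stood at 1.17 ± 0.73, Lgr5 at -0.29 ± 0.74, Padi3 at -0.10 ± 0.70 and Sox21 at -0.63 ± 0.41. In the mean of this list the lowest combination library, at 0.48, lay below the highest of the others, at 0.52. Skin taken with the tumour may therefore be a source of these transcripts but is neither shown nor excluded. Skin gained or changed by the treatment stays open as an untested biological explanation.

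MHC class I genes were higher with ICB. After group means were removed, the MHC class I list followed the interferon gamma list, with which it shares no gene, over the 12 libraries (r = 0.991, exact permutation p = 0.000772, the smallest that 1296 permutations can give, 0.00154 adjusted; rho = 0.993, p = 0.000772; r = 0.976 without the 2 farthest libraries). It also followed the leukocyte lists (r = 0.714, exact p = 0.0255, 0.0255 adjusted; rho = 0.769, p = 0.0170; r = 0.725 without the 2 farthest and 0.514 without combination replicate 3). Interferon acting on the tumour and more leukocytes both remain possible explanations of the rise. The correlations were taken within groups, so they do not test the rise between groups. The MHC class I and interferon gamma lists may also follow the same response, so their close correlation names no cause. In combination replicate 3 MHC class I differed from the mean of the other 2 by -2.08. Its macrophage list differed by -0.17, but its T cell list stood at 0.07 against 1.06 and 1.15 and its cytotoxic lymphocyte list at -0.17 against 1.67 and 1.58, so this library does not part the 2 explanations.

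Combination replicate 3 was low in interferon and MHC class I genes. An exchange with a vehicle library is argued against by its macrophage and monocyte list, 2.43 above the highest vehicle library. An exchange with a birinapant library was not tested. The MHC class I and interferon gamma lists of combination replicate 3, 5.42 and 3.20, lay just below the birinapant range, 5.55 to 5.80 and 3.28 to 3.89. Its macrophage and monocyte list, 3.93, lay above that group's 2.08 to 3.09, and its keratinocyte list, 6.90, above -1.10 to -0.73. Dilution by skin is argued against as well: against the other 2 combination libraries its melanoma list changed by -0.19 and its type I interferon list by -2.52, so the fall of the first was 7.37% of the fall of the second. Its T cell and cytotoxic lymphocyte lists were also below those of the other 2, at 0.07 and -0.17, and it had 1 count of Ifng against 17 and 21. ICB replicates 2 and 3 had lower T cell levels, -0.13 and -0.06, yet higher MHC class I levels, 6.50 and 6.43 against 5.42. Their cytotoxic lymphocyte lists were higher, at 0.55 and 0.31, and ICB replicate 3 also had 1 count of Ifng. Fewer lymphocytes and less interferon gamma may be a cause in combination replicate 3, but these values go both ways. The keratinocyte and fibroblast lists were highest in this library, at 6.90 and 5.23. Which cells gave the RNA of its T cell list was not tested, so its T cell level may not follow its T cells. No biological explanation was tested. The labels set this library apart from the other 2 by its title number, 15 against 7 and 8, without saying what it marks.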

How the results depend on the processing

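The keratinocyte covariate and the fit without combination replicates 2 and 3 were chosen after the data were seen. Counts of called genes follow in the order birinapant, ICB and combination against vehicle, combination against ICB and against birinapant, interaction, birinapant averaged and ICB averaged (8, 330, 1638, 52, 224, 0, 23 and 790 by edgeR, where the interaction had 699 at an unadjusted p under 0.05). RLE scaling kept each within 1.5 times. No named gene past the threshold turned its direction under DESeq2, RLE scaling, the replicate block or without 1 library, and none lost its call under DESeq2. Under the replicate block 7 of 7 (birinapant), 20 of 67 (ICB), 15 of 118 (combination), 11 of 17 (against ICB), 18 of 41 (against birinapant), 12 of 16 (birinapant averaged) and 17 of 95 (ICB averaged) lost it. Among panel genes DESeq2 added 11 calls under ICB, 2 in the combination, 6 against birinapant, 5 for birinapant averaged and 1 for ICB averaged. The other alternatives were not compared gene by gene for the named genes.

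DESeq2 called 222 (birinapant), 677 (ICB), 298 (combination against ICB), 550 (against birinapant), 16 (interaction), 965 (birinapant averaged) and 1205 (ICB averaged). Voom with quality weights gave 2, 779, 2876, 0 (combination against ICB, 1760 unadjusted), 142 and 1265 (averaged). The deposited log2 table gave 17 (birinapant), 31, 127 and 137 (birinapant averaged). Fits of only the 2 groups gave 50, 605, 0 and 0 (combination against ICB and birinapant, 1677 and 1291 unadjusted). No count filter gave 68 for birinapant averaged. With a mean count of at least 50, where fewer genes are tested, there were 218 (ICB), 1054 (combination), 7, 120 and 489 (ICB averaged).

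The replicate block gave 0 (birinapant, 1718 unadjusted), 209, 15, 124 and 6 (birinapant averaged). The numbers do not pair the libraries: residual correlations of equal numbers had a median of -0.0119 over 18 pairs, and 2 of 12 libraries correlated best with their own number. A covariate for a title number of 8 or lower against higher gave 27 (birinapant) and 144 (birinapant averaged). The keratinocyte covariate gave 4 (birinapant), 0, 0, 0 (combination against vehicle, ICB and birinapant), 0 (birinapant averaged) and 2 (ICB averaged); it is high in each combination library and low in the others, so its effect and the group's are hard to part. Under it 1483 of 1638, 37 of 52, 177 of 224 and 774 of 790 called genes kept their sign (combination against vehicle, ICB and birinapant, and ICB averaged). Without combination replicates 2 and 3, where the lone library is assumed to vary like the others, there were 710, 0, 111 and 9 (birinapant averaged).

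Leaving out 1 library each gave 0 to 24, 64 to 229, 722 to 1492, 0 to 292, 1 to 500, 0 to 9, 1 to 293 and 493 to 978 genes, and 16 to 20, 18 to 21, 21 to 23, 13 to 21, 21 to 25, 14 to 22, 17 to 21 and 21 to 28 lists. Of the named genes past the threshold, 7 of 7, 50 of 67, 43 of 118, 17 of 17, 41 of 41, 16 of 16 (birinapant averaged) and 28 of 95 (ICB averaged) lost their call without at least 1 library.

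An estimated correlation left 0, 5, 0, 0, 2, 0, 0 and 6 lists, and fry left 0 (birinapant), 0 (combination against ICB), 8 (against birinapant), 0 (interaction) and 6 (birinapant averaged). With the keratinocyte covariate 13 lists passed for the combination against vehicle, 11 of them among the original 21 in the same direction, and 8 against ICB, 3 of them among the original 14. Against vehicle it ended, among others, neutrophils (adjusted p = 0.445), NF-kB and TNF targets (0.215) and hypoxia and glycolysis (0.816). Some list calls turned. The type I interferon list for the combination against ICB passed as higher without combination replicate 3 (1.13e-06) and without replicates 2 and 3 (3.05e-05). With the keratinocyte covariate neutrophils passed as lower against ICB (0.00979) and birinapant (0.0390), skeletal muscle as lower against birinapant (0.00310) and for ICB averaged (0.00904), and red cells as higher against birinapant (0.0390). For the other changes the cause was not tested. Of the lists for NK cells and for B and plasma cells, 6 of 15 and 9 of 18 genes were in the count table and 4 each were tested; why the others are absent was not tested.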

Other observations

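Among the lists not described above, death and survival genes had few changes under birinapant, whose targets they include (0 of 32 past the threshold, 1 adjusted over the list alone, median log2 fold change 0.07, camera adjusted p = 0.656). In the combination 6 of 32 rose and 1 fell, and 9 rose and 2 fell adjusted over the list alone (adjusted p = 0.0145, and 0.235 with an estimated correlation). The risen genes include Tnfrsf1b, a TNF receptor (6.32-fold, adjusted p = 0.000108), Tnfsf10, which encodes TRAIL (12.9-fold), the inflammatory caspase gene Casp1 (7.87-fold) and the pore gene Gsdmd (6.08-fold). Of the noncanonical NF-kB list 4 of 15 rose in the combination, among them Cd40 8.44-fold, Tnfrsf11a 4.88-fold and Tnfrsf12a 1.52-fold, and 4 adjusted over the list alone, while the list did not pass (adjusted p = 0.332). Inflammatory chemokines rose in 1 of 14 under birinapant, 4 under ICB and 9 in the combination, such as Cxcl16 8.74-fold and Ccl4 16.9-fold (6, 7 and 11 adjusted over the list alone; adjusted p = 0.25, 0.0816 and 0.0891 with an estimated correlation).

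Proliferation genes had medians of 0.02, -0.07 and 0.08 under birinapant, ICB and the combination, with 0 of 31 past either threshold (adjusted p = 0.385, 0.0148 and 0.282, and 0.651 for ICB with an estimated correlation); the call under ICB was lost without vehicle replicate 2 (0.876) or ICB replicate 1 or 2 (0.0600 and 0.166). Endothelial genes (-0.11, -0.21 and 0.08) and regulatory T cell genes (-0.12, 0.06 and 0.46) did not pass in any of the 3. The mitochondrial list passed under birinapant (0.28, adjusted p = 0.00856, and 0.562 with an estimated correlation) without a called member, and lost its call without vehicle replicate 2 (0.123) or birinapant replicate 2 or 3 (0.143 and 0.0583). Dendritic cell genes rose in 3 of 11 under ICB and 4 in the combination (5 and 6 adjusted over the list alone; 0.104 and 0.185 with an estimated correlation), and adipocyte genes in 3 of 9 in the combination, Lpl 2.47-fold among them (3 adjusted over the list alone; 0.185 with an estimated correlation). The adipocyte list passed camera in the combination (adjusted p = 0.0161), but not without combination replicate 3 (0.0822). In the immediate early and heat shock list 4 of 20 rose in the combination and Nr4a1 fell 2.35-fold, with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.360). Ifng was below the count filter, with 0 counts in the vehicle libraries, 0, 5 and 3 under birinapant, 4, 4 and 1 under ICB and 17, 21 and 1 in the combination.

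Whether birinapant moves the genes that ICB moves was put as a test before its result was seen. Across 14715 genes the 2 averaged effects correlated at r = 0.676 (rho = 0.50), above the 95th percentile of 0.460 from 100000 relabellings of the libraries (one-sided permutation p = 0.00192). The relabellings mixed the libraries of all groups, so they assume that no treatment had an effect. The ICB response alone goes against that assumption, so the p does not show that birinapant moves these genes. The combination libraries, skin genes included, also enter both effects with the same sign. The hypothesis that birinapant alone starts a weaker form of the ICB response may hold, but this correlation cannot decide it. Scml4, higher under birinapant (3.39 ± 0.505 to 13.2 ± 4.01 CPM, SD, n = 3), stood at 4.66 ± 1.77 CPM with ICB and 6.62 ± 1.58 in the combination.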
